A study of Drosophila melanogaster with 2 samples.

How the data were processed

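Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on transgenic Drosophila melanogaster embryos that carried Six4 with green fluorescent protein (GFP) fused to its C terminus. Six4 is a homeodomain transcription factor of the sine oculis family. The antibody recognised GFP, so the measurement is of DNA recovered with the tagged protein. Per the labels, embryos were 0 to 16 hours old, whole animals of both sexes were pooled, and chromatin was fragmented by sonication to 200 to 800 bp. The labels give 2 samples, biological replicates 1 and 3 of 1 group. No second group and no control library was analysed here, so no comparison between conditions was made.

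The deposited values are lists of peaks. Per the file listing deposited with the samples, each replicate has a list of peaks and background intended as input for the irreproducible discovery rate (IDR) procedure. A list of the same kind was made from both replicates pooled, and the optimal IDR thresholded set was derived from the replicate lists and the pooled list. The listing names 1 further input of the replicate and pooled lists whose content it does not state. Every list was deposited on builds dm6 and dm3. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. Each peak has a signal value from the authors' peak caller and a −log10 q value, also the authors'. Signal values were used to rank peaks within a list and to compare median signal among promoter peaks. They were also plotted for peaks matched between the replicates. In the IDR set 2226 of 3974 peaks shared the highest −log10 q of 3.65, so ranks were taken from the signal. Read numbers were not analysed here and the depth of each library is unknown. Precision is therefore set by the number of peaks, and binomial intervals are exact (Clopper-Pearson, 95%) and cover counting error only.

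Coordinates are on dm6, counted from 1. The reference was the Release 6 genome with Ensembl 115 annotation (FlyBase 6.54), and chromosome names matched after removal of a prefix. The largest peak end on each of the 6 arms (2L, 2R, 3L, 3R, 4 and X) lay within the length of that arm. The dm3 lists were used for overlap and arm shares only, with the largest end in the lists as arm length.

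Tests were fixed before the data were examined, except where stated. For replicate overlap, the 3974 strongest peaks of each replicate, as many as the IDR set holds, were compared with a minimum overlap of 1 bp, against 1000 circular shifts of 1 list within each arm. The share of summits within 500 bp of an annotated transcription start site (TSS) was set against 1000 random placements on the same arms. Arm shares were compared with arm lengths by exact binomial tests. Tests of the arms other than X, and of locations other than promoters, were not among those fixed beforehand. For 21 gene lists, genes with 1 or more summits in the gene body extended by 2 kb on both sides were counted. Each count was set against 10000 random lists of protein-coding genes matched on the decile of window length. All 276 listed entries were found in the annotation, 4 of them under another symbol. For 13 motifs and all hexamers, windows of 100 bp to each side of the summit were compared with equal windows 1000 bp away on both sides. Exact McNemar tests used 1 of the 2 flanks per peak, chosen by a seeded coin. Tests against random sets were two-sided (the smaller tail doubled), except for replicate overlap, which was one-sided. Adjusted p-values are Benjamini-Hochberg values within the lists, motifs, arms, locations or hexamers, with a threshold of 0.05. These p-values treat peaks or genes as units and do not measure spread between replicates. Neighbouring peaks and genes are not independent, so they can be too small.

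Named genes followed a rule fixed before the data were examined. Six4 was always named, as were the genes with a TSS nearest to the 20 strongest IDR peaks. In each list up to 4 members with the strongest peak in their window and up to 2 without a peak were named, taken in list order. The result for 1 listed gene is not reported here. The 5 hexamers with the highest ratio among those past the threshold and in at least 2% of peaks were named too. A peak in the window of a listed gene can lie at the TSS of a neighbour, and cases where the nearest protein-coding TSS was that of another gene are stated.

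Alternatives fixed beforehand were other overlap rules, other numbers of peaks, dm3, other promoter and motif windows, other flank distances and other rules that give a peak to a gene. The 1987 strongest IDR peaks and each replicate's list alone were tried too. Alternatives added after the data had been seen are named as such in the closing section. Each statistic was tested on simulated data. Of 4000 simulated peaks with 75% shared, 75.5% were found as shared. A planted promoter share of 48.2% was recovered as 48.1%. Among lists with 80% of their members given a summit, 75.3% of 150 passed the adjusted threshold, and 1% of 100 random summit sets gave any list past it. TGATAC written into 2% of 4000 windows was recovered in 96% of 100 sets, and 8% of 100 sets without it gave p of 0.05 or less. All of 50 planted hexamers were recovered, and 0 passed in random sets. Random positions were drawn evenly along the arms. The rates of false calls therefore do not cover summits that concentrate at promoters or differ from their flanks in base composition. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, with seed 20.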

Results

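Binding of GFP-tagged Six4 was mapped by anti-GFP ChIP-seq in whole Drosophila embryos aged 0 to 16 hours. Both samples, biological replicates 1 and 3, belonged to 1 group. The peak lists of replicates 1 and 3 held 30000 and 28237 entries, background included, and the pooled list held 30000. The IDR thresholded set held 3974 peaks with a median width of 424 bp. It was identical to the 3974 strongest entries of the pooled list. Single peaks in it can therefore rank differently in the replicates, as the peak in the window of Pxn did (6274 in replicate 1 and 2485 in replicate 3). Library depths are unknown, and signal values are those of the authors' peak caller.

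The strongest sites of Six4-GFP recovery were the same in both replicates. The peak at the promoter of Ugalt, a UDP-galactose transporter, ranked 2 in replicate 1 and 1 in replicate 3. The peak at px, a gene of wing vein patterning, ranked 1 and 3. Over the 3974 strongest peaks of each replicate, 3115 of replicate 1 (78.4%, interval 77.1 to 79.7%) overlapped 1 of replicate 3. Shifted lists gave 2.23% on average and 3.20% at most (n = 3974 peaks, p = 0.000999, the smallest 1000 shifts can give). Agreement fell with rank: 99.6% of the first 500 peaks of replicate 1 had a partner, 81.0% of those ranked 2001 to 2500, and 43.2% of those ranked 3501 to 3974. Of the 859 peaks of replicate 1 without a partner, 808 (94.1%) overlapped an entry somewhere in the whole list of replicate 3, against 15.6% after shifting. Across the 3115 matched peaks Spearman's rho of the signal values was 0.748 and the median distance between summits was 27 bp. This correlation is across peaks, which are not independent replicates.

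**Figure D1:**
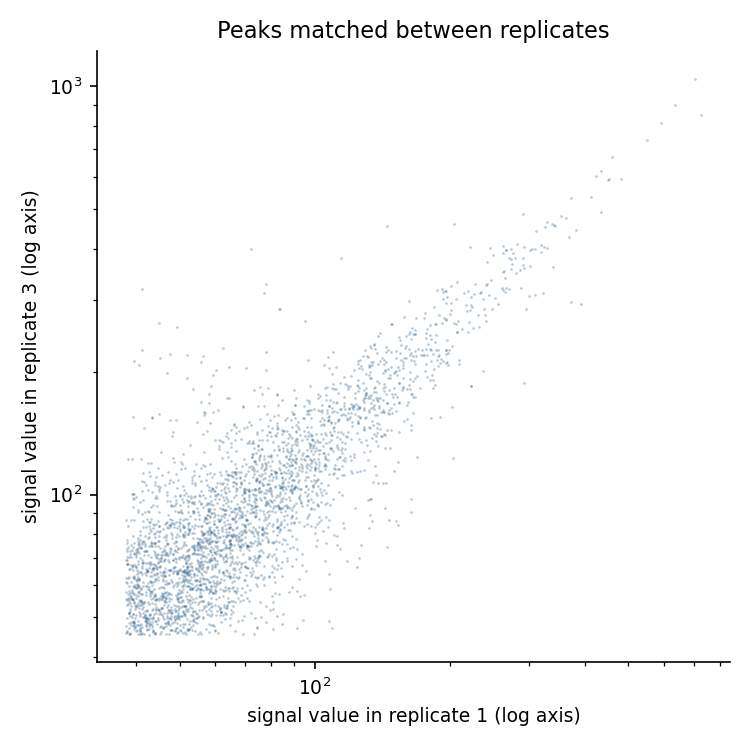
Signal value of each of the 3115 matched peaks in replicate 1 (horizontal, log axis) and replicate 3 (vertical, log axis), 1 point per peak. The cloud narrows toward high values, where the peaks at Ugalt (702 and 1044) and px (725 and 849) lie, and Spearman's rho was 0.748.

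The 20 strongest peaks lay mostly at promoters, 13 of them within 500 bp of a TSS. The highest signal, 1741, was at Ugalt on X (peak 2703689 to 2704081), with its summit at −26 bp from the TSS. It was followed by px on 2R (22514106 to 22514504, signal 1571, −206 bp) and CG14100 on 3L (19590439 to 19590812, signal 1532, −96 bp). Promoter summits were also found at Chro, a chromodomain protein (3L, signal 1126), Art3, a protein arginine methyltransferase (3R, 1068), and mRpL41, a mitochondrial ribosomal protein (2R, 1046). The same held for CenG1A (2L, 1032), ph-p, a Polycomb group protein (X, 1013), PNPase (3R, 946), Tcs5 (3L, 924), CG1888 (2R, 899), larp, a La-related RNA-binding protein (3R, 836), and Tina-1 (2R, 805). Intronic summits were nearest to CG11050 (2L, 1400, 1044 bp downstream), CG32772 (X, 842, 1270 bp downstream) and CG9663 (2L, 802, 939 bp downstream). The intronic summit nearest to cbt, a zinc finger transcription factor, lay at −1367 bp from its TSS (2L, 1310), and that nearest to the kinase gene Lk6 at −966 bp (3R, 1033). The other peaks of this rank were an exonic site 4992 bp downstream of the CG4004 TSS (X, 838) and an intergenic site 11882 bp downstream of CG13323 (2R, 829). In both replicates all 20 peaks ranked among the first 25.

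Six4 itself, on the minus strand of 3L (20788886 to 20792777), had 2 peaks in its window. The stronger lay at its promoter (20792808 to 20793231, summit 243 bp from the TSS) and ranked 2828 with a signal of 103. It ranked 2539 in replicate 1 and 3428 in replicate 3. Among genes of retinal determination, the network in which relatives of Six4 act, 4 of 11 were occupied, with 5.32 expected from length-matched genes (n = 11 genes, adjusted p = 1.0). The others were hth (intron, signal 181, rank 1092), so (105.8, 10062 bp from its own TSS and nearest to CG11145) and eyg (promoter, 92.4). No summit fell in the windows of Optix or of eya, which encodes a partner protein of Six4-type factors.

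Genes of the mesoderm and its derivatives, where Six4 is known to act, did not pass the adjusted threshold against length-matched genes under any rule, though mesoderm specification genes came near it under the nearest TSS rule. Of 18 mesoderm specification genes 10 had a summit, with 7.47 expected. With each peak given to its nearest TSS the count was 11, with 5.42 expected (n = 18 genes, raw p = 0.0118, adjusted p = 0.0619), and among the 1987 strongest peaks 9, with 4.69 expected (raw p = 0.05, adjusted p = 0.525). Among those peaks the lists of muscle identity (3, 6.04 expected), myoblast fusion (4, 4.06), sarcomere (5, 6.07) and somatic gonad (3, 4.13) lay below expectation. The strongest peak in the window of Mef2, a muscle transcription factor, ranked 24 (2R, 9959714 to 9960097, signal 778), 1058 bp from the Mef2 TSS but at the promoter of Pal1. Summits followed in an intron of zfh1 (365), at the promoter of tin (244, 232 bp from the TSS), which specifies the heart, and 1253 bp from bin (226). The windows of twi and sna had none. Of 20 muscle identity genes 8 were occupied (9.41 expected). These included org-1 (promoter, signal 341), Poxm (promoter, 268), tup (259, at the promoter of CG10602) and lbl (120, nearest to CheB93b), while slou and ap had no summit. Of 13 myoblast fusion genes 7 were occupied (6.24 expected), or 5 (6.26 expected) without replicate 3. The adhesion gene kirre held 12 peaks in a window of 398 kb (strongest 412) on X, an arm with 29.95 peaks per Mb. Intronic summits also lay in mbc (226), siz (201) and rols (149, nearest to CG6793). The kirre paralogue rst, and sns, had none. Of 24 sarcomere genes 7 were occupied (9.72 expected). Promoter summits were at sls (198) and Tm1 (187), and others at Zasp52 (182) and Zasp66 (174), but not at Mhc or Act57B. Of 13 somatic gonad genes 7 were occupied (6.29 expected), with summits at zfh1, Fas3 (191), Abd-B (185) and dsx (promoter, 109), and none at tj or shg. For the IDR set and gene windows the adjusted p was 1.0 for each of these lists.

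Ribosomal protein genes were the single list past the adjusted threshold. Of its 14 members 10 had a summit, with 3.84 expected and a central 95% range of 1 to 7 (n = 14 genes, adjusted p = 0.042). RpL32 had a promoter summit 136 bp from its TSS (signal 319, rank 314) and RpLP0 one 17 bp from its TSS (219). The strongest peak in the window of RpL3 (420) lay at the promoter of CG17726. RpL5 and RpL10 had none. The call was lost among the 1987 strongest peaks (8 of 14, 2.29 expected, n = 14 genes, adjusted p = 0.0546), where the ratio of the count to its expectation was no smaller, and with windows of 5 kb around each TSS (10 of 14, 5.73 expected, adjusted p = 0.165). Housekeeping genes were occupied in 10 of 14 cases with 5.04 expected (n = 14 genes, adjusted p = 0.183), led by the glycolytic genes Gapdh2 (promoter, 607) and Eno (promoter, 375), Hsp83 (intron, 310) and the actin gene Act5C (304, 640 bp from the nearest Act5C TSS). Gapdh1 and Tbp had no summit. Signalling genes were occupied in 11 of 15 cases with 7.39 expected (n = 15 genes, adjusted p = 0.425). Intronic summits lay in aos (484), N (313, nearest to CG18508) and sog (258), and a promoter summit at spi (330), but wg and hh had none. When each peak was given to its nearest TSS, signalling (n = 15 genes, 12 occupied, 5.20 expected, adjusted p = 0.0112) and housekeeping genes (n = 14 genes, 10 occupied, 2.48 expected, adjusted p = 0.0042) also passed.

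Segmentation genes were the least occupied of the embryonic lists, with 1 of 15 against 5.15 expected (n = 15 genes, raw p = 0.027, adjusted p = 0.189). The 1 member was slp1 (intergenic, signal 162), and eve and ftz had no summit. Under the nearest TSS rule 6 of the 15 were occupied, with 4.8 expected. Adult chemoreceptor genes, transcribed in sensory neurons of the grown fly, were occupied in 1 of 16 cases with 4.6 expected (n = 16 genes, adjusted p = 0.358). The summit in the window of Gr5a (111) was nearest to Tre1, and Or22a and Or42a had none.

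Markers of other embryonic tissues did not pass the adjusted threshold against length-matched genes either, each list with an adjusted p of 1.0 for the IDR set and gene windows. Such small lists have wide random ranges, 1 to 5 of 7 for glial genes, so moderate differences could be missed. Within 5 kb of a TSS the count of neuronal function genes was 3 (7.77 expected, n = 15 genes, raw p = 0.0228, adjusted p = 0.165). In the nervous system, 6 of 15 neuronal function genes (7.48 expected), 4 of 12 neuroblast genes (4.30) and 4 of 7 glial genes (2.87) had a summit. The strongest was at the promoter of elav, the pan-neuronal RNA-binding protein (500, rank 103). Others lay at nSyb (153, at the promoter of Bgb), and 1 peak (167, at the promoter of CG34283) lay in the overlapping windows of ChAT and VAChT, with brp and Syt1 empty. Neuroblast genes with a summit included grh (intron, 226.5), insc (promoter, 154), pros (120.5, nearest to mRpL40) and D (81.5), but not ase or wor. Glial genes were moody (promoter, 395), pnt (217), loco (141) and nrv2 (108, nearest to nrv1), with repo and gcm empty. In the blood and fat body, 4 of 13 hemocyte genes (5.88 expected) and 3 of 12 fat body genes (4.21) were occupied. The hemocyte count was unstable, at 2 without replicate 1 (n = 13 genes, raw p = 0.0484, adjusted p = 0.275) and 2 without replicate 3 (raw p = 0.0474, adjusted p = 0.296). The window of ush held the rank 5 peak nearest to cbt (1310), while the peaks at Pxn (89.2, at the promoter of CG42245), gcm2 (86.3, nearest to Trx2) and Pvr (81.9) were weak, and gcm and Hml had none. The fat body peaks were at Adh (163, at the promoter of Adhr), Lsp2 (129, at the promoter of DEF8) and mdy (107), with srp and svp empty.

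In epithelial tissues, 3 of 9 tracheal genes (4.11 expected), 4 of 9 epidermal genes (4.28) and 3 of 8 genes of endoderm and hindgut (3.38) had a summit. Leaving out replicate 1 lowered the endoderm and hindgut count to 1, and leaving out replicate 3 lowered the tracheal count to 2. Among tracheal genes these were rib (intron, 299.8), trh (promoter, 192) and bnl (81.3), with btl and vvl empty. Epidermal genes were grh, sn (162), ovo (135) and Ddc (81.3), with sha and f empty. The gut genes were fkh (promoter, 189.5), cad (102.5, nearest to Pomp) and lab (86.3), with GATAe and srp empty. Of 10 germline genes 4 were occupied (3.70 expected), with promoter summits at bgcn (166), piwi (112), nanos (105, nearest to CG11779) and gcl (97.3, nearest to CG14767), and none at vas or pgc. Without replicate 3 the count was 6 (3.66 expected), and within 5 kb of a TSS it was 8 (4.4 expected, n = 10 genes, raw p = 0.0472, adjusted p = 0.165). Of 8 Hox genes 5 were occupied (4.22 expected), but without replicate 1 the count was 3, below its expectation of 4.24. These included Abd-B, Antp (161), Dfd (promoter, 113) and lab, while pb and Scr had no summit. In all, 4352 of 13945 protein-coding genes (31.2%) had a summit in their window.

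**Figure D2:**
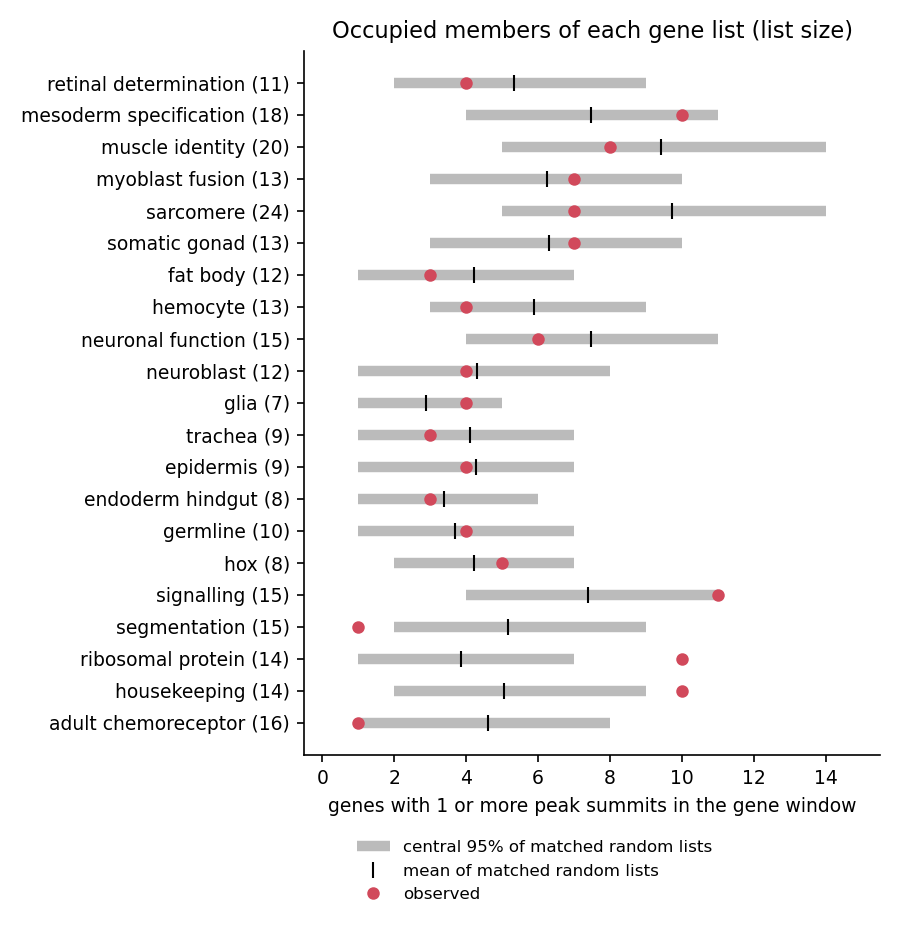
Number of genes with 1 or more summits in the gene body extended by 2 kb (horizontal), for each of 21 gene lists (vertical, list size in parentheses). Points are observed numbers, grey bars the central 95% of 10000 length-matched random lists and ticks their means. Ribosomal protein genes (10 of 14, 3.84 expected) and housekeeping genes (10 of 14, 5.04 expected) stood to the right of their bars and segmentation genes (1 of 15, 5.15 expected) to the left.

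Peak summits concentrated just upstream of gene starts and avoided coding sequence. Of 3974 summits, 1979 (49.8%, interval 48.2 to 51.4%) lay within 500 bp of a TSS. Random placement gave 13.6% ± 0.53 (SD, 1000 placements), so the share was 3.67-fold higher (n = 3974 summits, p = 0.002, the smallest 1000 placements can give). Among these promoter summits 83.4% were upstream of the nearest TSS, and the median position was −116 bp. Just 8 summits (0.201%) fell in coding sequence outside promoters, against 13.7% at random, and 25 (0.629%) in 3′ UTRs, against 4.41%. Introns held 34.1% (39.4% at random) and intergenic sequence 13.8% (27.4% at random), both below random placement (n = 3974 summits, adjusted p = 0.0028). Untranslated 5′ sequence beyond the promoter held 20 summits (0.503%, 0.777% at random, n = 3974 summits, adjusted p = 0.0396), and other exons 39 (adjusted p = 0.254). The 500 strongest peaks were at promoters in 61.2% of cases and those ranked 3501 to 3974 in 44.9%. In the lower-ranked 15000 entries of the pooled list, a reference added after the data had been seen, 22.2% were at promoters.

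**Figure D3:**
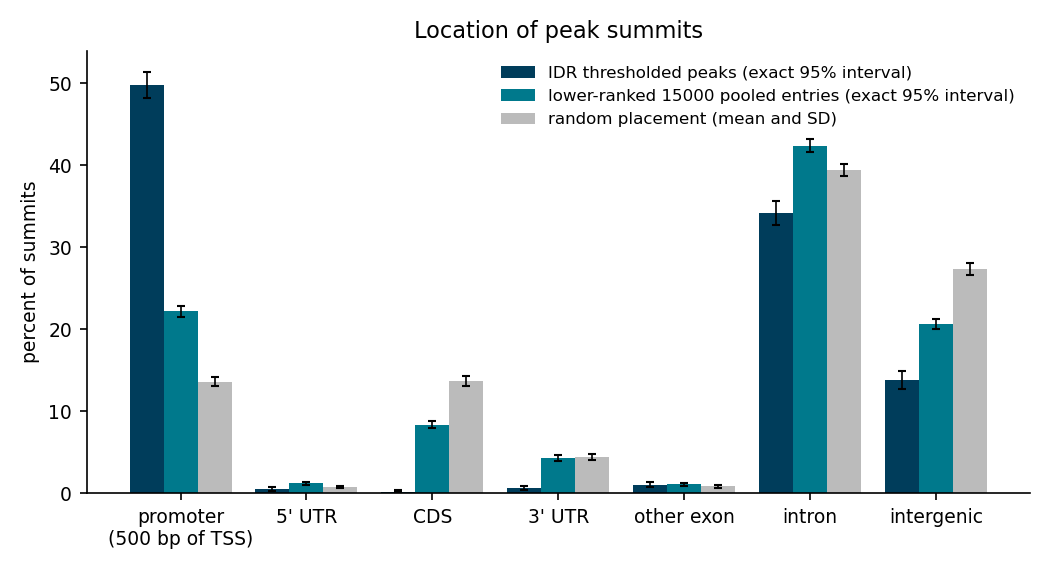
Percent of summits (vertical) in each kind of sequence (horizontal) for the 3974 IDR peaks, for the 15000 lower-ranked entries of the pooled list and for random placement. Error bars are exact 95% intervals for both peak sets and the SD of 1000 placements for the random set. Promoters held 49.8, 22.2 and 13.6%, and coding sequence 0.201, 8.34 and 13.7%.

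Chromosome 4 carried few peaks for its length, and the share of X did not differ from its length. Of the arm tests, that of X alone was fixed beforehand. X held 705 peaks (17.7%, interval 16.6 to 19.0%), or 29.9 per Mb, against 17.6% of the summed arm length (exact binomial p = 0.787). The small, largely heterochromatic chromosome 4 held 12 (0.302%, interval 0.156 to 0.527%) against 1.01% of the length (ratio 0.30, exact binomial adjusted p = 2.49e-06). Arm 2L held 760 peaks (ratio 1.09, exact binomial adjusted p = 0.0207) and 2R held 684 (ratio 0.911, adjusted p = 0.0199), and neither passed against the arms' shares of all pooled entries (adjusted p = 0.62 for both), a reference added afterwards. Arms 3L (881 peaks, exact binomial adjusted p = 0.105) and 3R (932, adjusted p = 0.549) did not differ from their share of length. In pooled male and female embryos X is present in fewer copies than autosomes, which these shares do not correct for.

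The core of the Six4-type binding site was modestly more frequent at summits than beside them. TGATAC occurred within 100 bp of 258 summits (6.49%, interval 5.75 to 7.30%) against 4.34% in flanks, a ratio of 1.5 (exact McNemar test, adjusted p = 0.00143). The call was lost with windows of 50 bp (ratio 1.49, exact McNemar adjusted p = 0.182) or 250 bp (ratio 1.13, adjusted p = 0.322), and 12 of the 102 hexamers made of the same letters had higher ratios. MEF3, a longer target site of the family, was found at 47 summits (ratio 0.74, exact McNemar adjusted p = 0.448), and the site of sine oculis at 9 (ratio 1.5, adjusted p = 0.879).

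Sites of core promoter factors showed larger ratios. The DNA replication-related element TATCGATA was at 135 summits (3.40% against 0.579%, ratio 5.87, exact McNemar adjusted p = 1.23e-18). The M1BP site GGTCACACT was at 53 (1.33% against 0.302%, ratio 4.42, exact McNemar adjusted p = 1.48e-06), which did not pass within 50 bp (ratio 3.0, adjusted p = 0.141). A/T-rich sites followed, the Mef2 site at 546 summits (13.7% against 6.56%, ratio 2.10, exact McNemar adjusted p = 1.69e-26) and the homeodomain site TAATTA at 732 (18.4% against 11.8%, ratio 1.57, adjusted p = 2.62e-18). In the lower-ranked entries of the pooled list, a reference added afterwards, the ratios were 2.74 for M1BP and 1.57 for TATCGATA. The Mef2 site had 1.04 there and TAATTA 0.934. A smaller excess of both core promoter sites was thus also present outside the IDR set, though no p-value belongs to it. These sites were not split by distance from a TSS, so a part of promoter position in their ratios was not tested. Summit windows had 35.0% G and C against 42.5% in flanks. Those of the lower-ranked pooled entries had 41.45% against 41.83%, so the contrast with these entries does not correct for composition. The Mef2 site and TAATTA were not compared with other words of the same letters. Base composition therefore remains a candidate explanation of their ratios. Sites of the early and mesodermal factors Zelda (ratio 0.77, exact McNemar adjusted p = 0.452), Tinman (1.03, 0.478) and Twist (1.15, 0.0621) did not pass, nor did those of GATA factors (1.01, 0.879), Su(H) (0.88, 0.879) and GAGA factor (0.99, 0.879). Zelda passed as less frequent at summits without replicate 1 (ratio 0.634, exact McNemar adjusted p = 0.0303) and with windows of 250 bp (ratio 0.728, adjusted p = 0.0451). GAGA passed with windows of 250 bp (ratio 1.69, exact McNemar adjusted p = 6.98e-17), and the Twist site against windows 2000 bp away (ratio 1.38, adjusted p = 0.000516).

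**Figure D4:**
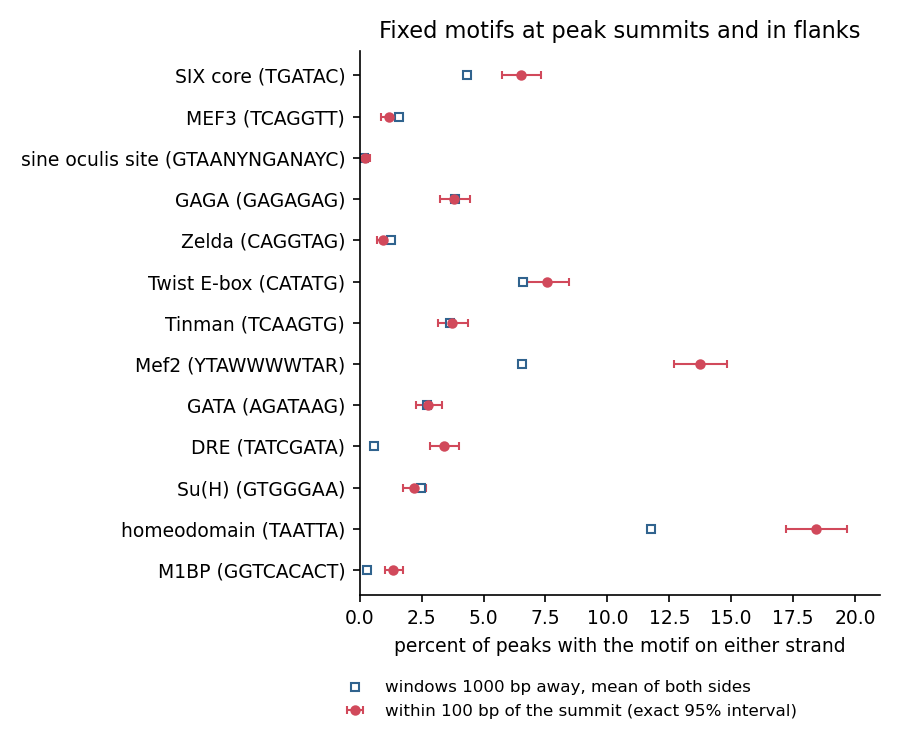
Percent of the 3974 peaks with each of 13 fixed motifs on either strand (horizontal), within 100 bp of the summit (filled circles, exact 95% interval) and in windows 1000 bp away (open squares, mean of both sides). TATCGATA was in 0.579% of flanks and 3.40% of summit windows, and TGATAC in 4.34 and 6.49%.

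Without choosing a motif beforehand, the hexamers that led within 100 bp of summits were variants of CAGTGT, but within 50 bp they were not among the leading 5. Of 2080 hexamers, each counted with its reverse complement, 491 were more frequent at summits and 983 less frequent. AGTGTA was within 100 bp of 17.1% of summits against 6.87% of flanks (ratio 2.48, exact McNemar adjusted p = 6.06e-48), ACACTG 18.1% against 7.51% (ratio 2.41, adjusted p = 7.92e-44) and ACAGTG 18.5% against 8.51% (ratio 2.18, adjusted p = 9.06e-36). CGATAG, which shares 5 bases with the DNA replication-related element, was at 9.56% against 4.45% (ratio 2.15), and ATATTA at 34.9% against 16.4% (ratio 2.13). Within 50 bp of summits the leading 5 were ATATTA, CGATAG, GTAATA, ATATAA and AATATT, and none of the CAGTGT variants was among them. Windows of 100 bp to each side of summits held less G and C than flanks (34.97% against 42.54%). The scan used no reference of equal composition, so the part of base composition in these ratios and counts was not tested.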

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

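The limit on q used here was set only after the lists had been examined. Outside the IDR thresholded set, the pooled list held 2548 further entries with a q value of 0.01 or less, a signal in data that the comparisons of the report did not use. Of these entries 99% overlapped an entry in the lists of both replicates, background included, and 43.5% lay within 500 bp of a TSS. The pooled list was made from both replicates, so this overlap is no independent support for these entries. With them included, 11 of the 14 ribosomal protein genes were occupied, with 5.29 expected, and no gene list passed the adjusted threshold by the matched random list test, against 1 for the IDR set alone. No group held enough samples for a test of single samples that stand apart, and no comparison between groups existed.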

How the results depend on the processing

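The references of same-letter hexamers, lower-ranked pooled entries and pooled arm shares, the q limit of 0.01 and the 8-base words were chosen after the data had been seen. Replicate overlap stayed past its threshold under every overlap rule, number of peaks and build tried (71.3 to 81.1%), and so did the promoter share (38.6 to 60.4% over windows of 250 to 1000 bp). The X share passed under none. The 3974 strongest pooled entries are the IDR set, so that alternative tests nothing. The count of gene lists past the threshold, 1 for the IDR set, was 0 among the 1987 strongest peaks, 3 with the nearest TSS, 0 within 5 kb of a TSS and 0 with entries of q up to 0.01. The TGATAC ratio of 1.5 was no longer past the threshold among the 1987 strongest peaks (1.41), where fewer peaks were tested, within 50 bp (1.49) or within 250 bp (1.13). It was 1.32 times the median ratio of same-letter hexamers, to which no p-value belongs. Hexamers higher at summits numbered 491, and 8-base words 1618 out of 32896 tested, more than the 2080 hexamers. For the other changes the cause was not tested. With each replicate left out in turn, the X share was 17.2 to 18.3%, the promoter share 49.6 to 50.6%, the lists past the threshold 1 and 1, the TGATAC ratio 1.32 to 1.35, and the hexamers 463 to 471. No call changed direction, but the X share, past no threshold, fell below its expectation without replicate 3 (17.2 against 17.6%) and on dm3 (18.0 against 18.6%). Among single lists and motifs 4 calls were lost (ribosomal proteins in 3 settings, M1BP in 1) and 6 gained (Zelda in 2, GAGA, Twist, signalling and housekeeping genes in 1 each). Lists past no threshold have no called direction, and up to 7 of 21 (nearest TSS) changed side of their expectation. No paired analysis was possible because there was 1 group. Unknown library depth and the lack of an analysed control library limit all results.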

Other observations

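The 8-base words, the comparisons by distance from a TSS, the tests of stronger against weaker peaks, the promoter share of lower-ranked entries and the count of 1 start per peak were chosen only after related results had been seen. Some whole gene families, picked by their symbols, stood apart from length-matched genes. These families include genes of the ribosomal protein and adult chemoreceptor lists, so they are no independent support for the results of those lists. Of 92 cytosolic ribosomal protein genes 64 had a summit in their window, with 22.1 expected from length-matched genes (n = 92 genes, adjusted p = 0.00076). With each peak given to its nearest TSS the count was 53, with 14.9 expected. Mitochondrial ribosomal protein genes were occupied in 35 of 73 cases (14.7 expected), but the nearest TSS rule gave 13 against 9.84 (n = 73 genes, adjusted p = 0.613), so many of those peaks were nearest to a neighbouring gene. Families used mainly in sensory neurons, cuticle and detoxification were seldom occupied. Counts were 3 of 59 odorant receptors (15.7 expected), 5 of 60 gustatory receptors (16.6), 6 of 60 ionotropic receptors (18.6), 7 of 120 cuticle proteins (26.7) and 5 of 85 cytochrome P450 genes (26.2). The proteasome (15 of 48, 12.0 expected), translation initiation factors (17 of 44, 14.1) and complex I (12 of 40, 9.77) did not pass. The hypothesis that families differ by chance alone was tested over 19 families: 7 passed the adjusted threshold, 2 above and 5 below expectation, and 6 of them also passed on the same side with the nearest TSS.

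The 8-base word that led at summits was CACTGAGA, within 100 bp of 4.38% of summits against 0.44% of flanks (ratio 9.94, exact McNemar adjusted p = 1.01e-28). It was followed by the overlapping words TACACTGA (ratio 7.78), ACTGAGAG (6.90) and ACACTGAG (6.78), then by TATCGATA. It was present at 137 of 1995 peaks farther than 500 bp from a TSS (6.87% against 0.501% of flanks) and at 37 of 1979 promoter peaks (1.87% against 0.379%), and the difference between these classes was not tested. Around 179 copies at summits, the base before the word was A or G in 93.9%, the base before that T in 59.2%, and the next 4 bases after the word A or G in 93.9, 87.2, 92.7 and 88.3%. Farther out no base exceeded 38.5% before the word or 43.6% after it, so the copies do not share a long repeat. The arms hold 4330 copies, of which 187 (4.32%) lay within 100 bp of a summit. No factor was assigned to this word.

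Genes with the most peaks in their window were CG1677 (14, in 129 kb), kirre (12, in 398 kb) and CHES-1-like (11, in 31.0 kb). Hr4 (in 70.0 kb) and Raf (in 52.4 kb) also held 11. All were named after their values were seen, and the counts were not corrected for window length.

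TGATAC was 1.5-fold more frequent at summits than in flanks over all peaks, where base composition remains a candidate explanation, since its ratio stood at percentile 88.2 of the 102 hexamers of the same letters. Promoter position does not account for it: the ratio was 1.96 at peaks farther than 500 bp from a TSS (7.62% against 3.89%, exact McNemar p = 1.38e-06) and 1.12 at promoter peaks (p = 0.666), and both differed (Fisher's exact p = 0.00351). At the peaks away from a TSS TGATAC had the highest ratio of all 102 hexamers in windows of 100 bp. It stood at percentile 98.0 in windows of 50 bp. These values argue against composition alone at these peaks, though the narrower windows lie within the wider ones. The reference was applied to these peaks only after related results had been seen. At promoter peaks the percentiles were 46.1 and 57.8. Whether binding of the tagged protein to the motif is the source cannot be told apart from other causes. The odds of the motif in stronger against weaker peaks were 0.984 (interval 0.764 to 1.27) over all peaks and 1.06 (0.761 to 1.48) away from a TSS, which excludes neither a modest rise nor a fall.

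The promoter share of 49.8% may have a technical part, since open promoter chromatin can be recovered by many antibodies. The lower-ranked 15000 pooled entries had 22.2% at promoters, below the interval of 48.2 to 51.4% but above the 13.6% of random placement. This argues against a bias of equal size in all entries of the lists. It cannot exclude a bias that also raises the signal, because entries were ranked by signal. Unspecific recovery of strongly transcribed promoters stays open: the 59 peaks at promoters of ribosomal protein genes had a median signal 1.07-fold that of other promoter peaks (interval 0.921 to 1.33, permutation p = 0.441). This ratio covers only peaks already in the IDR set, so it cannot show whether such promoters are called more often. Of the 92 cytosolic ribosomal protein genes 64 had a summit in their window, with 22.1 expected, which such recovery could also give. No biological explanation was tested, because the design has 1 group and no control library was analysed here.

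Divergent gene starts, which have a start of the opposite strand within 1 kb upstream, were occupied more often than others. They made up 63.8% of the 2134 occupied starts, against 31.5 to 35.2% in random sets of that number, which argues against chance over promoters. A summit near both starts of a pair counts for each, but with 1 start per peak, the nearest, the share was still 49.4% of 1515 peaks, above the 23.2 to 27.5% of random positions near gene starts. Among lower-ranked pooled entries it was 28.3%. Whether this reflects Six4 or the open chromatin such pairs share was not tested.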
